A study of Homo sapiens with 4 samples.

How the data were processed

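The series holds m6A-seq of HTR8/SVneo trophoblast cells in normoxia and after 12 h at 2% oxygen, with 1 m6A pulldown library and 1 input library per condition, 4 libraries in all. Per the labels' protocols, polyadenylated RNA was selected with a Dynabeads kit, and fragmentation, pulldown with a Synaptic Systems m6A antibody and library preparation followed a published protocol. The input libraries had no antibody step. Per the submitters' processing notes, Bowtie was used (no version given) and the genome build was hg38. The peak caller, its threshold and any scaling for library size are not given in the sources used here.

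The authors deposited 2 peak lists, 1 per condition, each of peaks called in that condition. Per the file headers, each peak has a gene ID, a RefSeq transcript with a start and an end on that transcript, an enrichment value in normoxia and in hypoxia, a transcript part and a mark for overlap with the other list. The list's own condition comes first, which was used to tell the lists apart, and its column never lies below 0.93 in either list, whereas the other column does. The deposited enrichment values are on a log2 scale. The base was settled from the values, because 2 raised to the value is a ratio of whole numbers with a denominator of at most 20000 (relative tolerance 2e-14) for 95.0% to 95.9% of values, against at most 0.619% with base 10 or e. The header does not say what is divided by what. The values were taken as pulldown over input in the same condition, which is an assumption, and differences between conditions were computed only at the same window. The authors' mark for common peaks was the same as an overlap of at least 1 base in every peak of both lists.

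Since no counts were used here, library depth is unknown and no value per peak has an error. With 1 library per group, no test between conditions was possible, and no p-value is given. Shares of peaks have exact Clopper-Pearson 95% intervals, which cover counting error only and treat peaks as independent. Gene IDs were matched to symbols through a RefSeq gene table of GRCh38.p14, and 6205 of 6210 IDs matched. Chromosome positions of genes come from that table, and peak positions are 1-based on the transcript.

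Overlap was counted on transcript coordinates with a minimum of 1 shared base and gave the same counts in bedtools 2.31.1. For the overlap expected by chance, each peak was moved at random within its transcript, up to the last base that any peak of either list reaches, 1000 times, because transcript lengths were not used here. To set the conditions side by side per gene, peaks of both lists were merged into 11277 regions, and a gene's difference is the median over its regions of hypoxia minus normoxia.

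Before the data were examined, 16 gene lists with 407 entries were fixed: HIF target and hypoxia response, glycolysis, m6A machinery, trophoblast identity, epithelial-mesenchymal transition and matrix, TGF-beta pathway, Hippo and YAP, immediate early and stress, cell cycle, apoptosis, chromatin and zinc finger regulators, cytosolic ribosomal proteins, oxidative phosphorylation, angiogenic and preeclampsia-linked genes, fibroblast markers, and endothelial and blood markers. For each list, the number of genes with a peak in each condition, the median difference and the median of the highest peaks were placed among 10000 random lists. Each random list held as many genes as the list had with a peak, drawn from the 6214 genes with a peak in either list. Members without any peak are thus left out of these percentiles. Matching on transcript length had been planned and was not possible, so the main random lists are unmatched. A percentile beyond 2.5 or 97.5 is a description of these libraries. The rule for named genes was also fixed before the data were examined. It takes the 10 genes with the highest peak per list, up to 4 members of each gene list per peak list by highest peak, the HIF and m6A machinery lists in full, and the top 5 genes with peaks in both lists. Other genes named, such as those listed as present in one list or without a peak, were chosen after their values were seen.

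The code was tested on simulated data. It recovered 100% of 2000 simulated whole-number ratios and called 0% of random values a ratio. For the gene lists, hypoxia minus normoxia over 6214 genes, 3% of 200 simulated null lists of 20 genes fell outside the 95% band, and 87.5% of lists shifted by 0.5 log2 did. Alternatives were the better scoring 50% of each list, merged peaks, other rules for overlap, gene names through the transcript accession, subsets by gene type and peak width, another gene background, random lists matched on genomic gene length, and a normoxia list shortened to the length of the hypoxia list. The motif content of peaks and the reassignment of transcript parts need a genome sequence and were not analysed here. The sizes of the whole-number ratios were also tried as a stand-in for coverage, in a pair of tests and an alternative. The tests addressed a 3' lean of the hypoxia reads and coverage at the HIF genes with peaks in hypoxia alone. A later look covered the whole HIF list. All of these were withdrawn after their results were seen, because they read counts out of decimals, and none of their values is used. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.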

Results

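Sites of N6-methyladenosine (m6A), the most abundant internal modification of mRNA, were mapped by antibody pulldown and sequencing (m6A-seq) in HTR8/SVneo cells. HTR8/SVneo is an immortalised line derived from human first-trimester placental cells and is used as a model of extravillous trophoblast. Cells were kept in normoxia or at 2% oxygen for 12 h. Polyadenylated RNA of each condition gave 1 library from the m6A antibody pulldown and 1 input library, which makes 4 libraries in all. The comparison addresses how the m6A landscape of trophoblast cells differs between low and normal oxygen. The files used here are 2 peak lists, 1 per condition, with no read counts, so the depth of the libraries is unknown. With 1 library of each kind per condition there is no replicate check, and no difference between conditions below was tested. Every enrichment value of a peak is the authors' own, on a log2 scale. Values of a gene are those of its highest peak in a list unless stated, and its other peaks can differ in direction. Binomial intervals are exact Clopper-Pearson 95% intervals that cover counting error only.

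The normoxia list held 8562 m6A peaks on 5337 transcripts and the hypoxia list 7094 peaks on 4432 transcripts, a ratio of 1.21 in peaks and 1.20 in transcripts. Peaks covered 1583 kb of transcript sequence in normoxia and 1235 kb in hypoxia. The median peak width was 174 bases in the normoxia list and 170 bases in the hypoxia list, with a lowest width of 100 bases in both. A transcript with any peak carried on average 1.60 peaks in either list, and 3318 normoxia transcripts and 2782 hypoxia transcripts had a single one. HUWE1, which encodes a large E3 ubiquitin ligase, and SYNE2, which encodes a giant nuclear envelope protein, carried 10 normoxia peaks each, the most in that list. SYNE2 also led the hypoxia list with 16 peaks, ahead of HSPG2 (perlecan), KMT2D and WNK1 with 9 each. mRNA accessions took 8377 of the normoxia peaks and 6950 of the hypoxia peaks. Peaks on noncoding transcripts numbered 185 and 144, and peaks on ribosomal RNA genes 9 and 6.

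Of the normoxia peaks, 4339 (50.7%, interval 49.6 to 51.7) shared at least 1 base with a hypoxia peak on the same transcript. Of the hypoxia peaks, 4359 (61.4%, interval 60.3 to 62.6) shared at least 1 base with a normoxia peak. Peaks placed at random along the same transcripts overlapped the other list at 13% (SD 0.345 over 1000 shuffles) for normoxia and 15.9% (SD 0.406) for hypoxia. The observed shares were 3.90 and 3.86 times these values. The shuffle does not keep the lean of both lists to the 3' UTR, so these ratios mix shared position along the transcript with shared sites. The peaks without a partner numbered 4223 in the normoxia list and 2735 in the hypoxia list. Many of them lay on transcripts that carried a peak elsewhere in the other list, 1984 in the normoxia list and 1693 in the hypoxia list.

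At the level of genes, 3555 transcripts carried peaks in both lists, 57.2% (interval 56.0 to 58.4) of the 6214 with a peak in either. They made up 66.6% of the transcripts in the normoxia list and 80.2% of those in the hypoxia list. A further 1782 transcripts had peaks in the normoxia list alone and 877 in the hypoxia list alone. The transcripts with peaks in both lists include MYC, JUN and SLC2A1, whereas HIF1A, METTL3 and PGF were listed in normoxia alone and VEGFA, FTO and FOS in hypoxia alone. Being listed in one condition alone does not mean that enrichment was absent in the other. The FTO window, for one, had a normoxia value above the lowest value in the normoxia list.

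Most peaks lay in 3' UTRs, as annotated by the authors. The 3' UTR share was 57.5% (interval 56.4 to 58.5) of normoxia peaks and 63.7% (62.6 to 64.9) of hypoxia peaks. Coding sequence (CDS) held 25.5% (24.6 to 26.4) of normoxia peaks and 21.0% (20 to 21.9) of hypoxia peaks. The stop codon class held 11.6% (10.9 to 12.3) and 10.7% (10.0 to 11.5). Peaks at start codons (1.64% and 1.09%), in 5' UTRs (1.66% and 1.44%) and on noncoding transcripts (2.16% and 2.03%) were few. The intervals of the lists were separate for the 3' UTR, the CDS and the start codon, and overlapped for the stop codon, the 5' UTR and noncoding transcripts. The intervals treat peaks as independent and compare these lists, not the conditions. The CDS difference, hypoxia minus normoxia, was -4.52 points, and -1.56 points with the normoxia list shortened to the length of the hypoxia list by leaving out its lowest peaks, which put its 3' UTR share at 60.1%. With the better scoring 50% of each list the CDS shares were 19.995% and 13%, and the 3' UTR shares 64.8% and 74.5%.

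**Figure D1:**
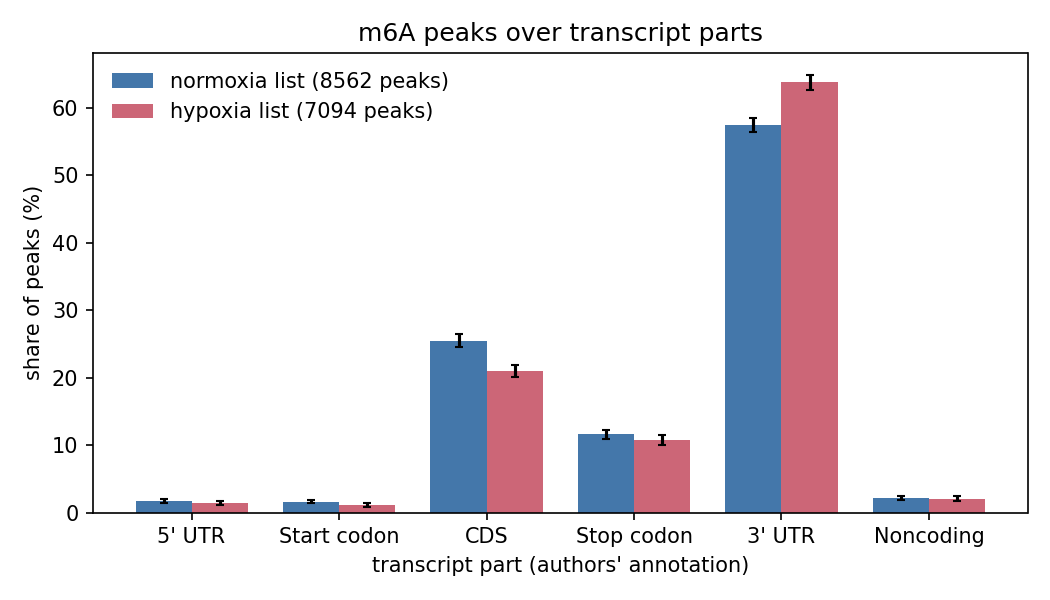
Share of peaks (%, vertical axis) in each transcript part of the authors' annotation (horizontal axis), for the normoxia list of 8562 peaks and the hypoxia list of 7094 peaks; error bars are exact 95% binomial intervals. The 3' UTR bar is 57.5% in normoxia and 63.7% in hypoxia, and the CDS bar 25.5% and 21.0%.

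The classes also differed in how often a peak was found in both lists. Stop codon peaks overlapped the other list most often, at 61.4% in the normoxia list and 74.8% in the hypoxia list. The share was 54.8% and 60.5% for 3' UTR peaks and 38.6% and 58.0% for CDS peaks. Among the peaks without a partner, CDS peaks made up 31.7% (interval 30.3 to 33.1) in normoxia and 22.9% (21.3 to 24.5) in hypoxia. The corresponding 3' UTR shares were 52.7% (51.2 to 54.2) and 65.3% (63.5 to 67.1). Among the peaks with a partner the shares were near equal, 19.4% and 19.8% for the CDS and 62.1% and 62.7% for the 3' UTR. Partner peaks overlap on the same transcript, so near-equal shares are built in.

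Each list gives the enrichment in both conditions at the same window, so that the conditions can be set side by side peak by peak. Within its own condition, the normoxia list had a median log2 enrichment of 1.53 and a range of 0.93 to 5.17. The hypoxia list had a median of 1.47 and a range of 0.93 to 5.61. At peaks shared by both lists the median difference, hypoxia minus normoxia, was -0.09 (quartiles -0.36 and 0.17) over the shared peaks of the normoxia list and -0.004 (quartiles -0.26 and 0.26) over those of the hypoxia list. With the better scoring 50% of each list these medians were -0.26 and 0.11. At peaks without a partner the median difference was -0.67 (quartiles -1.06 and -0.37) in the normoxia list and 0.63 (quartiles 0.36 and 1.02) in the hypoxia list. After peaks of both lists were merged into 11277 regions, 792 were higher in hypoxia by at least 1 log2 unit and 1256 were lower by at least 1 log2 unit. Most of these had peaks in a single list, which picks them on its own column. Of 2735 regions with hypoxia peaks alone 711 were higher, and of 4223 with normoxia peaks alone 1179 were lower. The counts therefore depend on how many regions each list holds alone, and cannot by themselves show or exclude a net loss. Of the 4319 regions with peaks in both lists, 66 were higher and 72 lower by that amount.

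**Figure D2:**
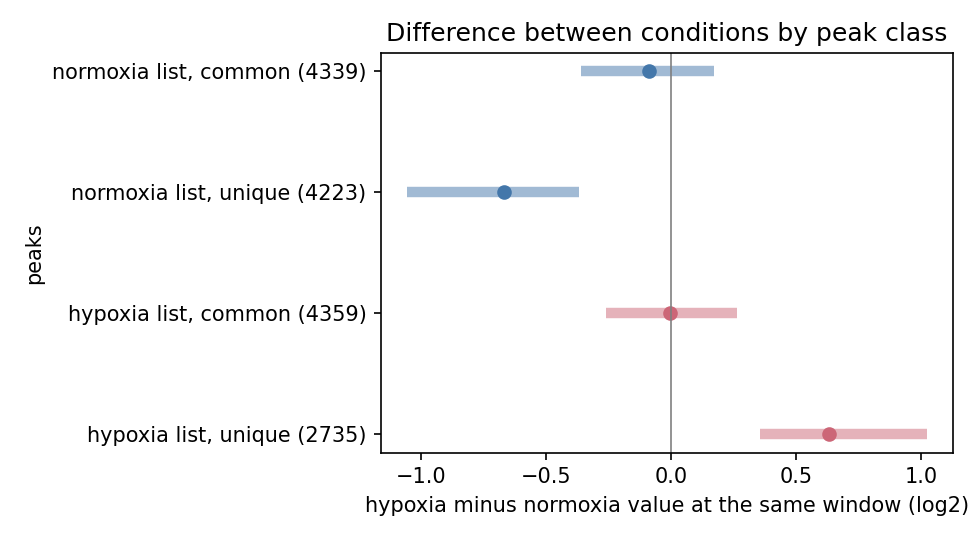
Difference in the authors' log2 enrichment at the same window, hypoxia minus normoxia (horizontal axis, log2), for the peaks of each list that do (common) or do not (unique) overlap the other list (vertical axis, number of peaks in brackets). Points are medians and bars run from the lower to the upper quartile; the medians are -0.09 and -0.67 in the normoxia list and -0.004 and 0.63 in the hypoxia list.

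The normoxia list was led by a 3' UTR peak of ETS2, which encodes an ETS-family transcription factor. This peak spans bases 3729 to 3897 of NM_001256295 (gene on chromosome 21, 38805183 to 38824955, GRCh38.p14). Its log2 enrichment was 5.17 in normoxia and 0.88 in hypoxia. The same transcript carried another 3' UTR peak (bases 2541 to 2750) that both lists shared, with 3.39 in normoxia and 3.43 in hypoxia. Next came PPP1R13B, which encodes a p53-binding protein of the ASPP family (4.98 in normoxia and -0.16 in hypoxia), and NFKB1, an NF-kappaB subunit (4.94 and 2.67). They were followed by ZFX (4.86 and 3.46), PLEKHM3 (4.81 and 1.42) and PDK1, the hypoxia-responsive pyruvate dehydrogenase kinase (4.74 and 1.92). TBC1D16 (4.67 and 1.42), SLC35A3 (4.58 and 0.32), PTGFR (4.57 and 3.51) and EDEM3 (4.56 and 0.58) completed the top 10. None of these 10 peaks overlapped a hypoxia peak. Even so, the hypoxia values of NFKB1, ZFX, PLEKHM3, PDK1, TBC1D16 and PTGFR lay above 0.93, the lowest value in the hypoxia list. Those of ETS2, PPP1R13B, SLC35A3 and EDEM3 lay below it.

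The hypoxia list was led by SNX7, which encodes a sorting nexin. Its 3' UTR peak covers bases 1588 to 1756 of NM_015976 (gene on chromosome 1, 98661319 to 98760500). It had a log2 enrichment of 5.61 in hypoxia and 2.02 in normoxia and overlapped a normoxia peak. KCNQ1OT1, an imprinted antisense noncoding RNA, followed with 5.17 in hypoxia and 3.39 in normoxia. HOXA13, a homeobox gene, had 4.66 in hypoxia and 1.0 in normoxia, and BCOR, a transcriptional corepressor, 4.66 and 3.39. The 5' UTR peak of the kinase gene CDC42BPA had 4.62 and 1.39, and LIN9, a subunit of a cell cycle regulatory complex, 4.48 and 0.70. The readthrough gene TPTEP2-CSNK1E (4.42 and 4.06) shares sequence with its component genes, and its assignment is uncertain. TMEM181 (4.39 and 1.67), DENND4C (4.37 and 2.58) and PAXIP1 (4.35 and 0.68) completed the top 10. Of these 10 peaks, SNX7's alone overlapped a normoxia peak. All but those of LIN9 and PAXIP1 had normoxia values above 0.93, the lowest value in the normoxia list. LIN9 and CDC42BPA also carried normoxia peaks at other positions, with 3.54 and 2.54 in normoxia against 1.04 and 0.48 in hypoxia.

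Genes with high peaks in both lists were ACVR2B, an activin receptor, EMSY (3.77 and 4.32 at the normoxia peak), OGT, the O-GlcNAc transferase (3.63 and 4.13 at the normoxia peak), FAM161A and FAM199X (3.69 and 3.96 at the normoxia peak). The windows of the lists did not overlap in ACVR2B and FAM161A. In ACVR2B the normoxia window had 4.07 in normoxia and 2.58 in hypoxia, and the hypoxia window 2.71 and 4.25. In FAM161A the normoxia window had 3.71 and 1.93, and the hypoxia window 0.65 and 3.57.

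Among the genes of the HIF pathway and the transcriptional response to hypoxia, 30 of 42 carried a peak, 25 in normoxia, 26 in hypoxia and 21 in both. The random lists held 30 genes with a peak in either list, so the 12 members without a peak do not count. The hypoxia count lay at the 97.4th percentile of 10000 such lists (mean 21.3), and the normoxia count at the 33.6th percentile (mean 25.8). With the better scoring 50% of each list the order was reversed, with the hypoxia count at the 13.4th percentile and the normoxia count at the 85.05th. Against all protein-coding genes both lay at the 100th percentile, but that background was not limited to expressed genes and cannot tell expression from methylation. Genes with peaks in hypoxia alone were VEGFA, the angiogenic growth factor, CA9, a carbonic anhydrase, ANKRD37, MXI1 and the histone demethylase gene KDM4B. The VEGFA peak, at bases 2731 to 2919 of NM_001171623 in the 3' UTR (gene on chromosome 6, 43770211 to 43786487), had 1.10 in hypoxia and 0.14 in normoxia. The highest CA9 peak, in the CDS, had 1.11 and 0.51, and its other CDS peak 1.0 in hypoxia and 1.41 in normoxia. The ANKRD37 peak had 1.46 in hypoxia and 0.65 in normoxia. The MXI1 peak had 1.48 and 1.14. KDM4B carried 4 hypoxia peaks with a median difference of 0.26, of which the highest had 1.26 in hypoxia and 1.33 in normoxia.

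Genes of the same group with peaks in normoxia alone were HIF1A, VHL, JMJD6 and P4HA2. HIF1A, which encodes the oxygen-regulated HIF subunit, carried 3 normoxia peaks with a median difference of -0.97. The highest, at the stop codon, covers bases 2821 to 3000 of NM_001530 (gene on chromosome 14, 61695513 to 61748258). It had 1.12 in normoxia and -0.47 in hypoxia. The CDS peak had 0.98 and 0.57 and the 3' UTR peak 1.12 and 0.14. VHL, the ubiquitin ligase component that targets HIF subunits, had 2.08 in normoxia and 0.63 in hypoxia, JMJD6 1.55 and 0.49, and P4HA2 1.05 and 0.68. EPAS1, which encodes a related HIF subunit, had separate 3' UTR windows with 1.71 in normoxia against 0.62 in hypoxia and with 2.01 in hypoxia against 0.64 in normoxia. Shared peaks included the glucose transporter gene SLC2A1 (1.80 in normoxia and 1.24 in hypoxia at the normoxia peak), PFKFB4 (2.21 and 1.29), BHLHE40 (2.75 and 1.91), P4HA1 (1.10 and 1.55), BNIP3 (1.03 and 1.05) and DDIT4 (1.48 and 1.51). No peak was listed for EGLN1, EGLN3, HILPDA or KDM3A among others. Over the 30 genes, 14 had a median difference above 0 and 16 below 0. The median of the group was -0.07, at the 67.0th percentile of random lists, whose central 95% ran from -0.40 to 0.14. The highest hypoxia peaks of these genes were low for the list, with a median of 1.26 at the 0.23rd percentile of random lists not matched on peaks per gene.

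Of the glycolysis genes, 14 of 20 carried a peak, all 14 in normoxia and 11 in hypoxia (94.1st and 70.8th percentiles). The normoxia count lay at the 14.4th percentile with the better scoring 50% of each list and at the 100th against all protein-coding genes. Peaks of GPI, PFKP and TPI1 were listed in normoxia alone. PGK1 had 1.48 in normoxia and 1.87 in hypoxia at a shared 3' UTR peak, PFKM 1.14 and 1.55, PFKL 1.13 and 1.43, and PKM 1.26 and 1.14. The other PFKL peak, in the normoxia list alone, had 1.10 in normoxia and 0.78 in hypoxia, and the median difference of the gene was -0.005. The highest HK2 peak of the normoxia list had 2.00 in normoxia and 0.88 in hypoxia. PDK1, among the top 10 genes of the normoxia list, is also a member of this group. Of the 14 genes, 4 had a median difference above 0 and 10 below 0. The median difference of the group was -0.09 (57.9th percentile).

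Of the genes for the m6A machinery itself, 18 of 21 carried a peak, 17 in normoxia and 11 in hypoxia, with 10 in both. Genes with peaks in normoxia alone were the methyltransferase components METTL3, METTL14 and WTAP, the methyltransferase METTL16, and the reader genes YTHDF1, YTHDF2 and IGF2BP3. FTO, a demethylase gene, had a peak in hypoxia alone, and VIRMA, CBLL1 and YTHDF3 had none. The METTL3 peak lies in the CDS (bases 1595 to 1767 of NM_019852, gene on chromosome 14, 21498138 to 21511340), with 1.38 in normoxia and 0.63 in hypoxia. METTL14 had 1.88 in normoxia and 0.49 in hypoxia, METTL16 1.44 and 0.14, WTAP 1.06 and 0.02, YTHDF2 1.32 and 0.54, YTHDF1 1.05 and 0.68, and IGF2BP3 1.63 and 1.33. The FTO peak had 2.10 in hypoxia and 1.72 in normoxia. The normoxia value of FTO and the hypoxia value of IGF2BP3 lay above 0.93, the lowest value in either list. The hypoxia values of the other genes with peaks in normoxia alone lay below it.

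At shared peaks, the demethylase gene ALKBH5 had 1.43 in normoxia and 1.34 in hypoxia, IGF2BP1 2.54 and 2.18, IGF2BP2 1.87 and 2.81, YTHDC2 1.99 and 2.58, and HNRNPA2B1 1.21 and 1.12. HNRNPC had 1.14 and 0.59 at its highest normoxia peak. RBM15 and RBM15B had 1.78 and 1.86 in normoxia against 0.85 and 1.17 in hypoxia at their highest normoxia peaks. At their highest hypoxia peaks they had 1.06 and 2.64 in hypoxia against 0.84 and 1.83 in normoxia, and the median differences of these genes were -0.33 and -0.03. The highest hypoxia peaks of ZC3H13 (2.32 in hypoxia and 0.76 in normoxia) and YTHDC1 (2.23 and 1.07) had no partner. The median difference over all peaks was -0.25 for ZC3H13 and 0.45 for YTHDC1. Of the 18 genes, 4 had a median difference above 0 and 14 below 0. The median difference was -0.31, at the 13th percentile of random lists (central 95% from -0.46 to 0.21), and at the 97.05th percentile with the better scoring 50% of each list. The counts with a peak lay at the 84.2nd percentile in normoxia and the 17.7th in hypoxia, and at the 100th and 99.85th against all protein-coding genes.

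**Figure D3:**
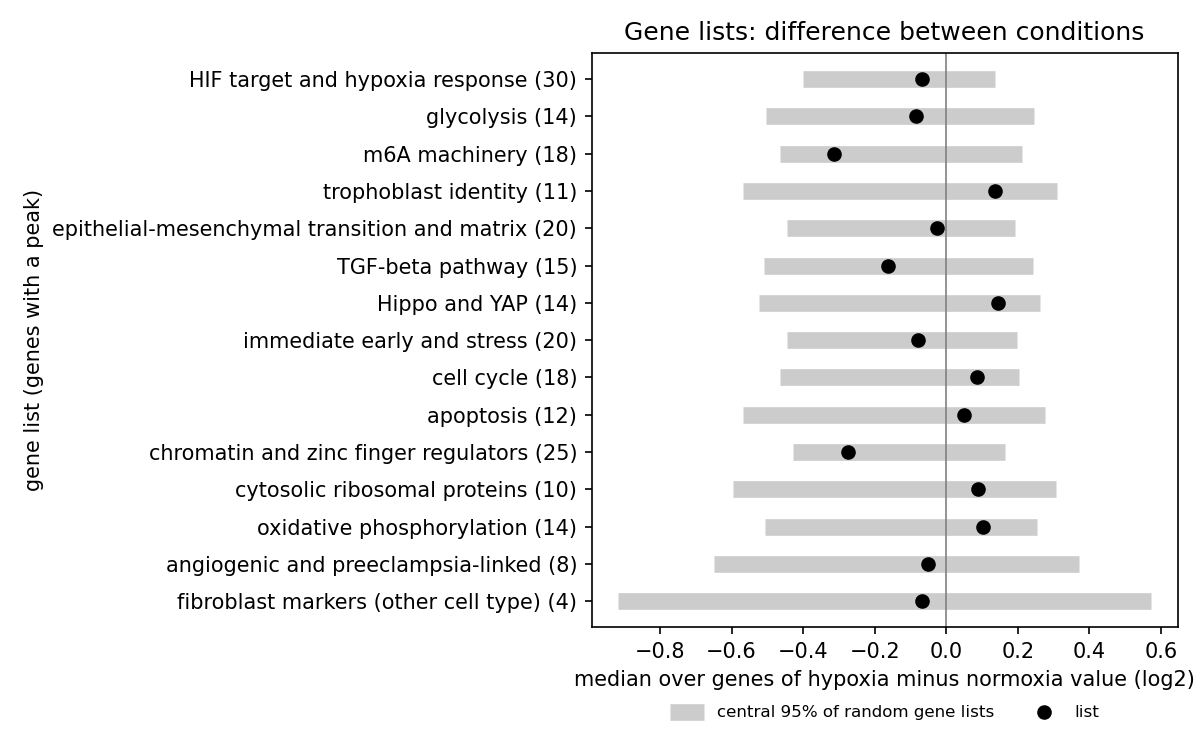
Median over genes of the difference in log2 enrichment, hypoxia minus normoxia (horizontal axis, log2), for the gene lists with more than 1 gene with a peak (vertical axis, number of such genes in brackets). Points are the lists and grey bars the central 95% of 10000 random gene lists of the size given in brackets. Every point lies inside its bar, and the points run from -0.31 to 0.14.

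Of 27 TGF-beta pathway genes 15 carried a peak, 12 in normoxia (random mean 12.9, 24.8th percentile), 7 in hypoxia (random mean 10.7, 2.59th percentile) and 4 in both. The hypoxia count lay at the 19.1st percentile with the better scoring 50% of each list and at the 71.05th against all protein-coding genes. SMAD1, SMAD5, SMAD6, SMURF1, SKI, ACVR1, BMPR2 and ID3 had peaks in normoxia alone. The difference, hypoxia minus normoxia, was small at the peaks of SKI (0.07) and ID3 (-0.16), and larger at those of SMAD1 (-1.19) and SMURF1 (-1.57). The receptor genes TGFBR1 and TGFBR2 and ID1 had peaks in hypoxia alone. The highest TGFBR2 peak had 2.63 in hypoxia and 0.55 in normoxia, that of TGFBR1 2.91 and 0.36, that of ACVR1 2.58 in normoxia and 1.84 in hypoxia, and that of BMPR2 2.24 and 1.05. The median difference of the group was -0.16 (43.4th percentile, and 3.50th with the better scoring 50% of each list). Of the Hippo and YAP genes, 14 of 20 carried a peak, 12 in each list (46.0th and 87.4th percentiles), and the highest STK4 peak, shared by both lists, had 3.70 in normoxia and 2.65 in hypoxia, although the median difference of the gene was 0.27. The median difference of the group was 0.14 (91.9th percentile).

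Of the trophoblast identity genes, 11 of 34 carried a peak, 8 in normoxia and all 11 in hypoxia (12.2nd and 98.7th percentiles). KRT8, HLA-C and ID2 had peaks in hypoxia alone. The integrin gene ITGA5 had 2.68 in normoxia and 2.15 in hypoxia at a shared peak, and TEAD4 2.21 and 1.96. HLA-G, GATA3, TFAP2C and KRT7 had no peak. With the better scoring 50% of each list the hypoxia count lay at the 97.2nd percentile, and against all protein-coding genes at the 92.6th. Of the genes linked to angiogenic signalling and preeclampsia, 8 of 25 carried a peak, 7 in each list. PGF, placental growth factor, had a 3' UTR peak in normoxia alone (bases 1604 to 1867 of NM_002632, gene on chromosome 14, 74941830 to 74955764), with 2.83 in normoxia and 0.88 in hypoxia. SMPD1 had one in hypoxia alone (2.19 in hypoxia and 1.39 in normoxia), and ENG, the endoglin gene, had a shared peak (1.64 in normoxia and 1.46 in hypoxia at the normoxia peak). FLT1 had no peak. The counts lay at the 51.6th and 82.3rd percentiles.

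Genes of the epithelial-mesenchymal transition and the matrix carried peaks in 20 of 30 cases, 19 in normoxia and 16 in hypoxia (87.2nd and 78.8th percentiles). The hypoxia count lay at the 22.7th percentile with the better scoring 50% of each list and at the 99.98th against all protein-coding genes. The transcription factor gene ZEB1 (2.56 in normoxia and 0.38 in hypoxia), THBS1 (4.49 and 2.85), TGFBI (3.0 and 0.62) and TIMP3 had peaks in normoxia alone, and COL4A1 in hypoxia alone. ZEB2 had separate windows, with 2.98 in hypoxia against 1.14 in normoxia at its highest hypoxia peak and 1.61 in normoxia against 0.57 in hypoxia at its highest normoxia peak. Of the immediate early and stress genes, 20 of 30 carried a peak, 19 in each list (87.9th and 99.3rd percentiles). The shared stop codon peak of MYC (bases 2503 to 2673 of NM_002467, gene on chromosome 8, 127735434 to 127742951) had 4.0 in normoxia and 3.56 in hypoxia. JUN had 2.68 and 3.06, GADD45B 2.47 and 1.62, and KLF10 2.58 and 2.18 at their normoxia peaks. FOS had a peak in hypoxia alone and IER3 in normoxia alone.

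Of the cell cycle genes 18 of 29 carried a peak, 18 in normoxia and 17 in hypoxia, with 17 in both (96.9th and 99.1st percentiles). The shared peaks of MKI67 (2.08 in normoxia and 2.10 in hypoxia), CCNA2 (2.26 and 2.12) and MCM4 (2.37 and 2.18) had near-equal values, and RB1 was listed in normoxia alone. Other members differed more, such as MDM2 and BUB1, with median differences of 1.45 and -0.59. Of the 18 genes, 12 had a median difference above 0 and 6 below 0, and the group median was 0.09 (89.0th percentile). Apoptosis genes with a peak numbered 12 of 24, 10 in normoxia and 8 in hypoxia (37.1st and 34.6th percentiles). CASP7 had 2.60 in normoxia and 3.91 in hypoxia at its shared normoxia peak, and APAF1 3.58 and 2.93. Of the chromatin regulators and zinc finger genes 25 of 28 had a peak, 24 in each list and 23 in both (93.1st and 99.9th percentiles). Their highest peaks were high in both lists (median 2.09 and 2.14, 98.5th and 99.4th percentiles). The random lists were not matched on peaks per gene, and a gene with more peaks has more chances of a high one. KMT2D carried 8 normoxia and 9 hypoxia peaks, against an average of 1.60 per transcript. With the better scoring 50% of each list, the hypoxia counts of the immediate early, cell cycle and chromatin groups lay at the 78.6th, 71.3rd and 94.2nd percentiles.

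Ribosomal protein genes and genes of oxidative phosphorylation carried low peaks. The random lists were not matched on peaks per gene, and a gene with few peaks has fewer chances of a high one. Of the cytosolic ribosomal protein genes 10 of 30 had a peak, 8 in normoxia and 9 in hypoxia (28.8th and 89.7th percentiles). Their highest peaks had a median of 1.04 in normoxia and 1.07 in hypoxia, at the 0.01st and 0.08th percentiles of random lists. Of the oxidative phosphorylation genes 14 of 26 had a peak, 9 in each list and 4 in both (2.32nd and 27.8th percentiles). Their highest peaks had medians of 1.15 and 1.22 (0.04th and 1.80th percentiles). The normoxia count of this group lay at the 3.65th percentile of random lists matched on genomic gene length, at the 24.4th with the better scoring 50% of each list, and at the 86.5th against all protein-coding genes. Fibroblast markers had peaks in 4 of 10 genes, THY1 in both lists, PDGFRB in normoxia and COL3A1 and ACTA2 in hypoxia (5.18th and 52.6th percentiles). Of 11 endothelial and blood markers ENG alone had one, in both lists (57.0th and 64.3rd percentiles). Percentiles describe these libraries and carry no correction for the 16 lists. The position of a list depended on the setting: across the lists with more than 1 gene in a setting, count percentiles ran from 13.4 to 97.4 with the better scoring 50% of each list, and from 35.6 to 100 against all protein-coding genes.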

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

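All tests in this part were chosen after the result was seen, except the test of different transcripts for the CDS share.

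At 107 peaks of the normoxia list the enrichment was above 0 in normoxia and below 0 in hypoxia, and at 62 peaks of the hypoxia list it was above 0 in hypoxia and below 0 in normoxia. They stand out because the sign of the enrichment differs between the conditions. As no own value lies below 0.93, the flag rests on the other condition's value alone. It holds 1.25% of the normoxia list and 0.87% of the hypoxia list. Any scaling for library size is unknown, so a value of 0 has no fixed meaning. The difference was not tested, as each condition has 1 pulldown and 1 input library. Of the 107 peaks 106 had no partner in the hypoxia list, and 46 lay in 3' UTRs and 36 in the CDS. The median was 1.82 in normoxia and -0.17 in hypoxia. None of the 62 overlapped a normoxia peak, and the median was 1.60 in hypoxia and -0.22 in normoxia. On the fixed gene lists they include HIF1A (1.12 in normoxia and -0.47 in hypoxia), CASP3 (1.67 and -0.14), TFAP2A (1.59 in hypoxia and -0.01 in normoxia) and ZEB2 (2.20 and -0.51). Outside the lists, and chosen after their values were seen, peaks with low values in the other condition were those of SLC4A7 (2.09 in normoxia and -1.65 in hypoxia) and HEATR5A (2.35 and -1.58) in the normoxia list, and ZNF8-ERVK3-1 (2.5 in hypoxia and -1.73 in normoxia) in the hypoxia list.

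Peaks without a partner were lower in the other condition in both lists, with median differences of -0.67 and 0.63. The opposite signs follow from how these peaks are picked, on each list's own column. The sizes were alike, with a sum of medians of -0.0386, but a gain and a loss of methylation of like size would give that too, so the sum does not separate selection from a gain or loss, which stays open as untested. Missed calls are another candidate explanation, since 43.3% (interval 41.8 to 44.8) of the normoxia peaks without a partner had a hypoxia value at or above the lowest value in the normoxia list. The corresponding share in the hypoxia list was 37.7% (35.9 to 39.6).

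The hypoxia list held a lower share of CDS peaks, by -4.52 points (interval -5.60 to -3.53, over 500 resamples of transcripts). Among peaks with a partner the CDS shares were near equal, 19.4% in the normoxia list and 19.8% in the hypoxia list. Different transcripts in the lists do not account for all of the lower share, since the difference was -3.18 points (-4.15 to -2.14) on transcripts with peaks in both. Weighted over 10 bins of equal enrichment, the difference was -5.51 points (-6.51 to -4.65). By the values given, the normoxia list did not hold weaker peaks, with a median of 1.53 against 1.47 in the hypoxia list. Scaling is unknown and the conditions need not share a scale, so this does not settle which list reached weaker sites. Since the CDS share falls with enrichment in both lists, this weighting was bound to leave the difference in place and adds no support. Shortening the normoxia list to the length of the hypoxia list left -1.56 points (-2.74 to -0.61), which decides nothing, because it takes the lowest peaks, the richest in CDS, from the normoxia list alone. A longer normoxia list, a lean of the hypoxia reads to the 3' end and a change of methylation by oxygen stay open. The stand-in test of a 3' lean was withdrawn, and a change of methylation was not tested.

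The HIF pathway genes VEGFA, CA9, ANKRD37, MXI1 and KDM4B had peaks in hypoxia alone. A missed normoxia call cannot be told apart from a difference in methylation here, because 2 of the 5 genes had a normoxia value at or above the lowest of the normoxia list at their highest hypoxia peak. Over all 877 genes with peaks in hypoxia alone that share was 39.8%. Higher transcript levels in hypoxia may also make a peak easier to call. They stay open, since no expression values were used here and the stand-in test of coverage was withdrawn.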

How the results depend on the processing

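The shortened normoxia list and the matching on genomic gene length were chosen after seeing the data. No paired analysis was possible because each group holds 1 library. Library depth is unknown, so its limits could not be measured. No gene list percentile moved from beyond the lower limit of the random lists to beyond the upper limit, or the reverse. Some did cross the middle of the random lists, such as that of the oxidative phosphorylation count in normoxia. This percentile went from 2.32 to 86.5 against all protein-coding genes.

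With the better scoring 50% of each list, 4281 normoxia and 3547 hypoxia peaks were left by construction. The overlap was then 38.6% of normoxia and 46.7% of hypoxia peaks, and 39.7% of transcripts had peaks in both lists. The 3' UTR share was 64.8% in normoxia and 74.5% in hypoxia, the CDS share 19.995% and 13%, and the stop codon share 10.4% and 8.68%. The median difference was -0.26 at common and -0.94 at unique normoxia peaks, and 0.11 and 0.94 at those of the hypoxia list, since higher own values were selected. At common hypoxia peaks the main median, -0.004, has an interval that includes 0. The CDS and 3' UTR differences between the lists kept their direction.

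Requiring an overlap of 50% of the smaller peak gave 48.9% of normoxia and 59.3% of hypoxia peaks. Counting peaks within 100 bases gave 53.1% and 64.1%. With the normoxia list shortened to 7094 peaks, the overlap was 51.6% of normoxia and 52.0% of hypoxia peaks, 52.9% of transcripts had peaks in both lists, and the normoxia list had 60.1% of its peaks in 3' UTRs and 22.5% in the CDS, by construction, as its lowest peaks lean to the CDS. Merging peaks left both counts as they were. Gene names through the transcript accession (57.2% in both) and the subsets by gene type and peak width stayed within the main intervals, though the width range removed no peak.

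For the gene lists, 95 of 117 alternative percentiles stayed on the same side of the limits of the central 95% of random lists. Against all protein-coding genes, 14 percentiles moved outside these limits and 2 inside, since genes with no peak then count. This background was not limited to expressed genes, so a high percentile against it cannot tell expression from methylation. For the HIF list the percentiles against it were 100 in normoxia and 100 in hypoxia, and for the m6A machinery 100 and 99.85. Inside the limits, the better scoring 50% moved the median difference of the m6A machinery from the 13th to the 97.05th percentile and the hypoxia count of the HIF list from the 97.4th to the 13.4th. It moved 5 other percentiles from outside to inside the limits and gene length matching 1. Motif variants, assignment of parts by summit or longest transcript, and matching on transcript length were not run.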

Other observations

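The values in this part were looked at after the data were seen and were not tested.

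Position and enrichment went together within each list. In the lowest 10% of the normoxia list by enrichment, 45.3% of peaks lay in the CDS and 39.4% in 3' UTRs, against 15.1% and 70.9% in the highest 10%. In the hypoxia list the CDS share was 47.2% in the lowest and 6.20% in the highest 10%, and the 3' UTR share 37.2% and 83.9%.

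The highest peaks were not the ones found most often in both lists. In the highest 10%, 39.0% (interval 35.7 to 42.3) of normoxia peaks and 50% (46.3 to 53.7) of hypoxia peaks overlapped the other list. Among 10 groups of equal size by enrichment, the share was highest in the third from the bottom in normoxia, at 59.0% (55.6 to 62.3), and in the fifth in hypoxia, at 70.1% (66.6 to 73.4). In the lowest 10% it was 42.0% and 46.1%. A test of whether thin coverage lies behind the highest values was not run, as no counts were used here.

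The highest hypoxia peaks of the 7 TGF-beta pathway genes had a median of 2.59 (99.9th percentile), those of the 11 m6A machinery genes 2.16 (98.5th percentile) and those of the 8 apoptosis genes 2.47 (99.5th percentile). The highest normoxia peaks of these groups, over different members (12, 17 and 10 genes), had medians of 1.81 (71.2nd percentile), 1.44 (8.04th percentile) and 1.60 (34.5th percentile). The highest normoxia peaks of the glycolysis genes were low at the median, 1.14 (0.02nd percentile), as were their highest hypoxia peaks at 1.27 (2.88th percentile). Not every member was low, since PDK1 was among the top 10 genes of the normoxia list. None of these random lists was matched on the number of peaks per gene, or on the number of genes with a peak in the list at hand. For the TGF-beta pathway the random lists had on average 10.7 genes with a hypoxia peak, against 7 observed. Medians over more genes spread less, so its 99.9th percentile may be overstated.

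At 116 windows both lists gave the same start and end, and both enrichment values were equal in the lists at all 116 (tolerance 1e-09).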
